A study of Oikopleura dioica with 67 samples.

How the data were processed

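Expression was measured by RNA sequencing in 2 sets of Oikopleura dioica libraries. The hemisphere set holds 24 libraries in 6 groups of 4 (animal hemisphere, vegetal hemisphere and whole embryo, at the 8-cell stage and at 12 hpf), and the staged set holds 43 libraries in 15 groups (13 stages with 3 libraries each, adult females and adult males with 2 each). Per the labels RNA was extracted with TRIzol, and the library kit was strand-specific for the staged set and not for the hemisphere set. The authors' deposited RPKM tables, made after HISAT2 alignment (version not given in the sources used here), hold values per kilobase of unigene, scaled by the number of reads, for 19277 unigenes of a de novo assembly. Counts of reads per library and lane, and the percent of reads aligned to the genome, are in a sequencing table of the staged set that the authors deposited. The authors' deposited table of 4-fold differences at 12 hpf gives a ratio of mean vegetal to mean animal RPKM and a p-value per unigene, by a test not given in the sources used here, and was used for a comparison of counts only. The authors' deposited counts of unigenes up or down against the egg, cluster numbers and BLAST e-values of a transcription factor list were read, and of these the factor list was used.

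Gene symbols are those of the staged table (10122 unigenes, 6496 distinct symbols, 1700 symbols on more than 1 unigene). The unigene IDs are not paired with the reference names table by the sources used here, so no symbol was taken from it. A second staged sheet differs in the symbols of 2724 unigenes and in 11 of 43 columns, which hold another library's values times a constant, so the first sheet was used. The stage labelled 2.5 hpf is headed 2 hpf there, and they were taken as the same. A further 95 columns with values per library were not used. No raw counts were used, and depth was read in 2 ways. In the staged set, reads per library ran from 7785352 to 95644620. In both sets the smallest steps between values under 1 RPKM gave a relative depth, from 0.807 to 1.42 in the hemisphere set (a 1.77-fold range) and from 0.222 to 2.91 in the staged set (13.1-fold). In 37 staged libraries it lay within 1.5-fold of the aligned reads after centring. Intervals for counting error were not computed, since counts per unigene were not used here.

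Values were analysed as log2(RPKM + 1). Unigenes with 1 RPKM or more in at least 4 libraries of the hemisphere set (15697) or 2 of the staged set (18704) were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with a mean for each group and a spread shared over all libraries of the set (18 and 28 residual degrees of freedom). P-values were adjusted by Benjamini and Hochberg over the unigenes tested, with a threshold of 0.05, and changes of 4-fold or more were counted too. Hemisphere differences are vegetal minus animal. Whole embryos were compared with the mean of the log2 values of both hemispheres, and adults as the mean of both sexes. Any difference among the 13 stages was tested with limma's moderated F-test, each stage was tested against the one before, and the first stage with a 4-fold rise over the egg was recorded. Sharing between 8 cells and 12 hpf, and presence in the egg at 1 RPKM (or 5), were tested with Fisher's exact test in R. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

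The samples, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule named, for each of 5 contrasts (hemispheres at 8 cells and at 12 hpf, tadpole against egg, juvenile against hatched larva, female against male), the 10 unigenes with the largest change in each direction among those that carried a symbol, passed the threshold and had groups that did not overlap, and up to 4 members with the smallest p from each list. At most 2 unigenes without a symbol were named per direction. Some genes that the rule selects are not reported here. Genes named elsewhere were chosen after their values were seen, which the text states.

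The 23 lists cover muscle, notochord, epidermis and house, endoderm and digestion, nervous system, germ line, cell cycle, histones, ribosomal proteins, oxidative phosphorylation, proteasome, Wnt, TGF-beta and BMP, FGF and MAPK, Notch and Hedgehog signalling, homeobox factors, T-box to ETS factors (T-box, bHLH, Fox, Sox, GATA, ETS), axoneme and sperm, meiosis, heat shock, extracellular matrix, splicing, and RNA quality with the mitochondrial genome. Members were read from the spelling of the symbol, which gave 1405 unigenes, 57 of them in more than 1 list. The epidermis and house list found 0 members and was not tested. The spelling brought in 83 unigenes of other function, such as Glipr2 in the Notch list and Psmc3ip in the proteasome list, and the tests were run again without them. Lists of at least 5 members were tested with camera of limma, with a preset correlation between genes of 0.01 and, as an alternative, an estimated one. The 8 mitochondrial unigenes were below the minimum in the hemisphere set.

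Alternative settings chosen then were a pseudocount of 0.1, no minimum, quantile normalization of the log2 values, no trend, a spread from the compared libraries alone, the replicate number as a block, and each replicate left out in turn. Alternatives chosen after seeing the data were the replicate number as a block within each time, the lane as a covariate, the second staged sheet, lists without members matched by spelling alone or with added symbols, leaving out the 2 libraries that stand apart (vegetal 12 hpf 3 and whole-embryo 8-cell 6), hemispheres of a number averaged as RPKM, and sharing among unigenes at 1 RPKM or more in 4 hemisphere libraries at each time. Whether the replicate numbers pair the hemisphere libraries was checked by the correlation of residuals across unigenes, which are not independent replicates. Within each time every pair of the same number was positively correlated (0.550 to 0.701 between animal and vegetal at 8 cells, 0.144 to 0.246 at 12 hpf), and across times not every pair was. Egg or 1.5 hpf and tadpole, and hatched larva and juvenile, were sequenced on different flow cells, whereas both sexes shared a lane.

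The tests were tested on simulated data in which 200 unigenes were changed. Changes of 2 on the log2 scale were recovered in 88.1% at the 8-cell stage, 76.1% at 12 hpf, 56.7% for the tadpole, 70.1% for the juvenile and 35.8% for the sexes, and those of 1 in 16.4%, 25.4%, 11.9%, 4.5% and 1.5%. False calls were 2.22% to 5.71% of calls.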

Results

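RNA of the larvacean tunicate Oikopleura dioica was measured in 67 libraries. In 24 of them, animal hemispheres, vegetal hemispheres and whole embryos were compared at the 8-cell stage and at 12 hours post fertilization (hpf), with 4 libraries in each of 6 groups, numbered 3 to 6. The other 43 libraries followed 13 stages from the unfertilized egg to the 10 hpf juvenile, with 3 libraries per stage, and 2 adult females and 2 adult males. Expression was given in RPKM for 19277 assembled unigenes, of which 10122 carried a gene symbol. The RPKM of a hemisphere library summed to between 824912 and 1121461, with 7821 to 15202 unigenes at 1 RPKM or more. In the staged libraries the sums ran from 739145 to 1234504, with 6277 to 17384 unigenes at 1 RPKM or more, and sequencing gave between 7785352 and 95644620 reads per library, of which 18.9% to 49.0% aligned. Differences are given as log2 ± SE of RPKM plus 1, which understates the change of weakly expressed genes, and expression as mean RPKM ± SD. Adjusted p-values are from limma. Nothing in the labels says that replicates came from separate cultures or animals, so each p measures the spread between these samples.

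At the 8-cell stage animal and vegetal hemispheres were compared. The RNAs that differed were higher in the vegetal hemisphere with a single exception, and those that carried a gene symbol included transcription factors, Wnt ligands and protein kinases (n = 4 libraries per hemisphere). ZIC4, a zinc-finger transcription factor, stood at 68.5 ± 63.8 RPKM in the vegetal and 0.49 ± 0.709 in the animal hemisphere, a log2 difference of 5.10 ± 0.59 (adjusted p = 9.07e-06). SNAI2, of the Snail family of transcriptional repressors, stood at 24.6 ± 4.61 against 0.438 ± 0.435 RPKM, or 4.19 ± 0.28 (adjusted p = 2.68e-09). A pair of unigenes named Wnt11 were vegetal-higher by 3.54 ± 0.25 and 3.51 ± 0.24, and Wnt4 and WNT4, also secreted Wnt ligands, by 3.20 ± 0.26 and 3.05 ± 0.26. Rnf128, a ubiquitin ligase, was higher by 3.84 ± 0.39 (43.6 ± 6.69 against 2.23 ± 1.16 RPKM). Otx2, a homeobox factor of the anterior nervous system in chordates, was higher by 3.58 ± 0.54 and Foxa2, a forkhead factor of endoderm and notochord, by 2.99 ± 0.49. The serine/threonine kinase PIM3 differed by 4.00 ± 0.58 and PIM1 by 3.68 ± 0.73. PAX3, a paired-box factor, stood at 43.8 ± 21.1 against 1.33 ± 1.26 RPKM (4.32 ± 0.88), and SALL1, a zinc-finger repressor, at 52.7 ± 33.2 against 1.62 ± 1.21 (4.29 ± 0.91). GLIS3 was higher by 3.23 ± 0.60 and Plk1, a kinase of mitosis, by 2.26 ± 0.44. In the whole-embryo libraries of the same stage, SALL1 was at 103 RPKM in number 4 and at 0.412, 0.255 and 0.557 in numbers 6, 5 and 3, whereas SNAI2 was between 8.63 and 12.7 RPKM in all 4.

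Of 15697 unigenes tested, 63 differed at the 8-cell stage, 62 vegetal-higher and 1 animal-higher, and 58 of them by 4-fold or more. Of the vegetal-higher unigenes 22 carried a symbol. The libraries did not overlap for the 63 and, called or not, for 1.2% of all tested, against 2.9% by chance without ties. The animal-higher unigene had no symbol (OD_K25COV4_DN20093_c0_g2_i1) and stood at 47.4 ± 36.1 RPKM in the animal and 0.165 ± 0.33 in the vegetal hemisphere. Gata2, a GATA factor, had means of 14.6 ± 6.94 vegetal and 69.5 ± 39.7 animal RPKM and did not pass (adjusted p = 0.0717, and 0.043 without animal library 3). HES1 was listed at 0 in the animal hemisphere and did not pass (adjusted p = 0.0867), but passed without vegetal library 4 (0.0168), with a pseudocount of 0.1 (0.00209) and under quantile normalization (0.0432). SALL1 was lost without any of the 4 animal libraries or without vegetal library 3 or 6 (adjusted p from 0.0512 to 0.152). PIM1 was lost without animal library 3, 4 or 6 or vegetal library 3 or 6 (adjusted p from 0.0532 to 0.0781). PAX3 was lost without animal library 4 or 6 or vegetal library 3 or 6 (adjusted p from 0.0716 to 0.1), GLIS3 without vegetal library 6 (0.0574) and Plk1 without vegetal library 4 (0.0565). Quantile normalization ended the calls of PAX3 (adjusted p = 0.172), SALL1 (0.1) and Plk1 (0.081), and a pseudocount of 0.1 those of PAX3 (0.146), SALL1 (0.172) and Plk1 (0.395). A fit of the compared libraries alone ended those of ZIC4 (adjusted p = 0.11), SALL1 (0.0889), GLIS3 (0.0752), Foxa2 (0.0677), PIM1 (0.0653) and of Otx2, PAX3 and PIM3 (0.0528 each). With the replicate number as a block within each time, the calls of SALL1 (adjusted p = 0.0889) and PIM1 (0.0509) were lost.

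**Figure D1:**
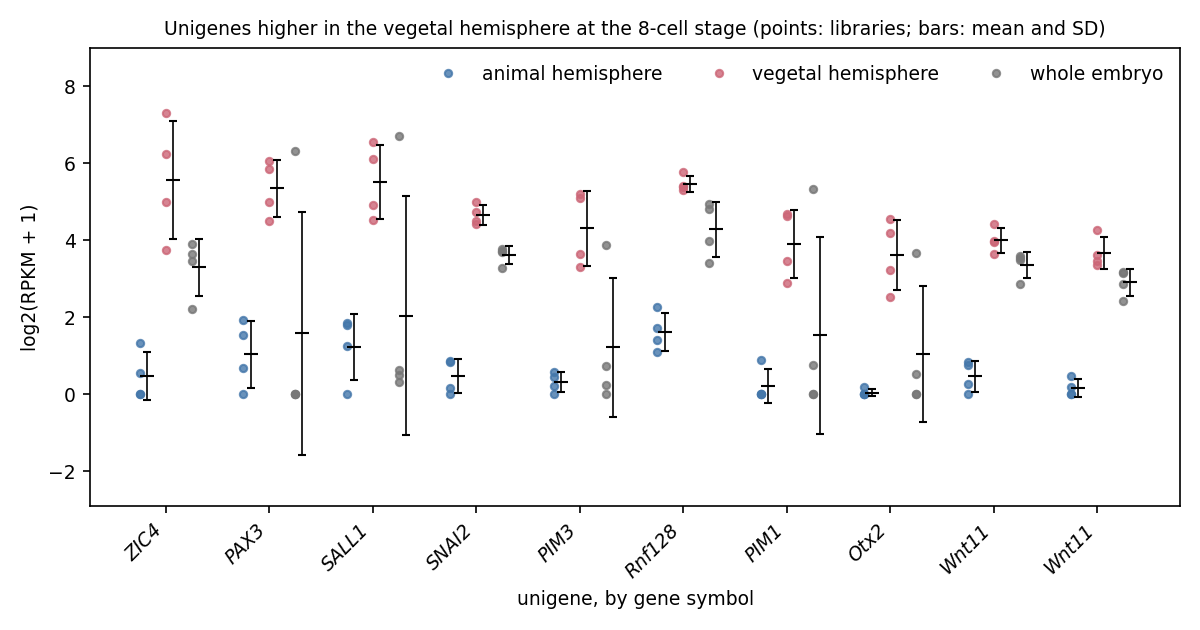
Expression on the log2(RPKM + 1) scale in each 8-cell library (points, 4 per group) of the 10 named unigenes with the largest vegetal-higher differences, in animal hemispheres, vegetal hemispheres and whole embryos, with bars for the mean and SD on that scale. The vegetal points of each gene lie above all its animal points, and for SALL1 (called in only some of the fits that leave out a library) whole-embryo library 4 (103 RPKM) lies apart from the other 3.

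Among gene lists at the 8-cell stage, Wnt signalling was shifted to the vegetal side: 4 of 30 members were vegetal-higher, 0 animal-higher and 26 did not pass (5 and 0 within the list), adjusted p = 3.73e-16, and 0.000309 with estimated correlation. The 4 carry only the names Wnt11 and Wnt4 or WNT4, and unigenes sharing a symbol may share reads. Counts within the list have p adjusted over its members alone. For the cell cycle list, 1 of 73 members was vegetal-higher, 0 were animal-higher and 72 did not pass (1 and 0 within the list), with the list shifted to the vegetal side (adjusted p = 0.0082, and 0.711 with estimated correlation). The germ line list was also shifted to the vegetal side (adjusted p = 0.0082, and 0.654 with estimated correlation) although no member passed, and Ddx4, an RNA helicase of the germ line, had means of 3.69 ± 0.901 vegetal and 1.74 ± 0.699 animal RPKM. Genes of cytosolic ribosomal proteins lay on the animal side with a median of -0.21 (adjusted p = 5.21e-22, and 0.654 with estimated correlation), and none of the 78 passed alone. The muscle list lay on the animal side as well (adjusted p = 0.000199, and 0.796 with estimated correlation), with no member passed. Under quantile normalization the ribosomal (adjusted p = 0.582), cell cycle (0.685) and germ line (0.685) shifts were lost, and the cell cycle shift was lost with the symbols of the second sheet added (0.0583). Transcription factors were not called as groups (adjusted p = 0.985 each). For homeobox factors 3 of 73 members were vegetal-higher, 0 animal-higher and 70 did not pass (3 and 0 within the list). For T-box to ETS factors 3 of 81 were vegetal-higher, 0 animal-higher and 78 did not pass (4 and 2 within the list). For Notch and Hedgehog signalling 1 of 38 was vegetal-higher, 0 animal-higher and 37 did not pass (2 and 0 within the list), with adjusted p = 0.758. In each of the endoderm (119 measured), neural (53) and notochord (27) lists 1 member was vegetal-higher. No member passed in the lists for the axoneme (109), extracellular matrix (91), oxidative phosphorylation (50), heat shock (51), meiosis (7), proteasome (40), histones (9), FGF signalling (31), splicing (119) and TGF-beta signalling (41), and none was called by camera of limma. With the block within each time the oxidative phosphorylation list was called (adjusted p = 0.0195 against 0.0732). At that stage 176 unigenes had an unadjusted p under 0.05, fewer than chance gives, so not passing does not show equality.

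Whether the RNAs unequal at 8 cells were those unequal at 12 hpf, and whether they were maternal, was tested with Fisher's exact test (two-sided). By this exact test, of the 62 vegetal-higher unigenes 8 were vegetal-higher at 12 hpf against 20.4 by chance (odds ratio 0.302, 95% interval 0.124 to 0.639, p = 0.000573), and 0 animal-higher against 9.52 (p = 5.49e-05). However, 44 of the 62 did not reach 1 RPKM in 4 of the 8 hemisphere libraries at 12 hpf, where a call was thus unlikely. Among unigenes that did so at each time, a test added after the results were seen, 7 of 18 were vegetal-higher at 12 hpf against 3.8 by chance (odds ratio 2.38, interval 0.783 to 6.75, exact p = 0.0797) and 0 animal-higher against 1.6 (exact p = 0.398). The vegetal-higher unigenes were less often present in the unfertilized egg of the staged set: 14 of 62 (22.6%) had a mean of 1 RPKM or more there, against 7926 of the 15635 others (50.7%; odds ratio 0.284, interval 0.144 to 0.524, exact p = 9.11e-06). At 5 RPKM the shares were 16.1% and 41.7% (exact p = 2.45e-05). ZIC4 had a mean of 0.0674 RPKM in the egg, 0.48 in staged 8-cell embryos, 32.1 at the 16-cell and 57.2 at the 32-cell stage. SNAI2 went from 0.778 to 9.84, 13.2 and 5.77, and Rnf128 was at 10.1 in the egg and 13.8 at the 8-cell stage.

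At 12 hpf the largest vegetal-higher differences among unigenes with a symbol included tubulins and digestive proteases, and the largest animal-higher ones other tubulins and the matrix proteins Hmcn1 and Agrn (n = 4 libraries each). The labels do not say how the hemispheres of this stage were obtained. In them the unigenes called higher in whole embryos by 4-fold or more stood at medians of 2.23% to 22.6% of the whole-embryo mean. Those unigenes were chosen for that difference in these libraries, so low values follow from the choice. The hemispheres may not add up to intact embryos, which these values do not test. An alpha-tubulin named Tuba3a stood at 4800.4 ± 2658 RPKM in the vegetal and 4.1 ± 4.63 in the animal samples, a difference of 10.13 ± 0.75, and another of that name differed by 9.69 ± 0.67. Tuba1b was vegetal-higher by 8.46 ± 0.41 and Cfap20, of the ciliary axoneme, by 8.85 ± 0.58 (785 ± 337 against 0.818 ± 1.26 RPKM). The trypsin-like proteases PRSS3P2 and PRSS3 were higher by 8.84 ± 0.63 and 8.54 ± 0.72, and CTRL, a chymotrypsin-like protease, by 8.53 ± 0.62. Anxa13, an annexin of the intestine in mammals, differed by 8.35 ± 0.69, BOLL, an RNA-binding protein of the germ line, by 8.25 ± 0.42 and FGG, a fibrinogen chain, by 8.15 ± 0.44. The largest adjusted p among these 10 was 5.18e-10. On the animal side, unigenes named Tuba1a differed by -5.68 ± 0.64 (6.3 ± 11.2 vegetal against 168 ± 74.2 animal RPKM) and -4.51 ± 0.50, and a Tuba3a unigene by -4.85 ± 0.55. Hmcn1, a matrix protein, stood at 74.1 ± 72.2 vegetal and 2050.4 ± 2213 animal RPKM (-5.21 ± 0.92), and Agrn, agrin of basement membranes, differed by -4.86 ± 0.84. UMODL1 and TECTB, of the zona pellucida domain proteins, differed by -5.31 ± 0.81 and -5.00 ± 0.73. Ust, a sulfotransferase, differed by -4.69 ± 0.72 and Pkd2l1, a cation channel, by -4.46 ± 0.61. The largest adjusted p of these animal-higher genes was 4.44e-05. Unigenes that share a symbol may share reads, and antisense reads were not told apart in these unstranded libraries.

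At 12 hpf, 7566 of 15697 unigenes differed, 5157 vegetal-higher and 2409 animal-higher, and 3834 by 4-fold or more (2674 and 1160). The libraries did not overlap for 5094 of these and, called or not, for 34.5% of all tested, against 2.9% by chance. Quantile normalization gives all libraries one distribution, which evens out directions and cannot test their balance. It gave 3437 vegetal-higher and 4105 animal-higher and moved the median difference from 0.304 to -0.204. Vegetal library 3 correlated less with its group than the others (mean 0.872), and its level of the unigenes that were animal-higher without it was a median 43.8% of the animal mean, against 2.42% to 10.1% in the other vegetal libraries. Without it 7969 unigenes differed, and without it and whole-embryo 8-cell library 6 the count was 8004, 5431 vegetal-higher and 2573 animal-higher. In the authors' deposited table of 4-fold differences at 12 hpf, 2389 unigenes were vegetal-higher and 466 animal-higher, of which 2331 and 458 were among the 4-fold differences found here.

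The lists called between the 12 hpf hemispheres were those of axoneme, muscle and endoderm, all vegetal-higher. With an estimated correlation all 3 calls were lost. Of the axoneme and sperm list, 96 of 109 members were vegetal-higher, 1 was animal-higher and 12 did not pass (96 and 1 within the list). The axoneme list had adjusted p = 1.07e-24, and 0.127 with estimated correlation. ENKUR stood at 152 ± 35.8 RPKM vegetal against 0.217 ± 0.214 animal, Rsph4a of the radial spoke at 108 ± 17.8 against 0.087 ± 0.109, and EFHC2 and the dynein chain Dnai1 were higher by 6.02 ± 0.24 and 6.01 ± 0.24. Of the muscle list, 68 of 91 members were vegetal-higher, 6 were animal-higher and 17 did not pass (71 and 6 within the list). The muscle list had adjusted p = 3.08e-11, and 0.542 with estimated correlation. The myosin light chain Myl6 was higher by 6.88 ± 0.33, troponins Tnni3 and Tnnc1 by 6.37 ± 0.34 and 7.40 ± 0.43, and CKM, creatine kinase, by 7.58 ± 0.43. Of the endoderm and digestion list, 66 of 119 members were vegetal-higher, 18 were animal-higher and 35 did not pass (67 and 19 within the list). The endoderm list had adjusted p = 0.000402, and 0.944 with estimated correlation. Carboxypeptidase CPB1 was higher by 7.10 ± 0.31, a Foxa2 unigene by 6.06 ± 0.29 and the peptide transporter SLC15A1 by 5.06 ± 0.24. These 3 lists kept their calls under quantile normalization. Without the 2 libraries that stand apart the vegetal-higher members numbered 96 for the axoneme, 72 for muscle and 66 for endoderm.

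The other lists were not called at 12 hpf, and most held members on both sides. In the extracellular matrix, 30 of 91 members were vegetal-higher, 33 were animal-higher and 28 did not pass (30 and 33 within the list), with adjusted p = 0.449. LAMA1, a laminin chain, stood at 377 ± 127 RPKM vegetal and 0.493 ± 0.42 animal, and the collagen COL9A1 was higher by 6.21 ± 0.36. For homeobox factors, 23 of 73 members were vegetal-higher, 17 were animal-higher and 33 did not pass (23 and 17 within the list), with adjusted p = 0.812. PAX9 stood at 24 ± 7.38 RPKM in the vegetal samples and was listed at 0 in the animal samples, and NKX2-1 and SIX6 were vegetal-higher by 5.16 ± 0.35 and 5.07 ± 0.38. For T-box to ETS factors, 32 of 81 members were vegetal-higher, 19 were animal-higher and 30 did not pass (32 and 19 within the list), with adjusted p = 0.88 and Foxd1 at 153 ± 32.3 RPKM vegetal and 0.389 ± 0.369 animal. Of the neural list, 28 of 53 members were vegetal-higher, 4 were animal-higher and 21 did not pass (29 and 4 within the list), with adjusted p = 0.14 and GAD1, which makes the transmitter GABA, higher by 3.60 ± 0.27 and SLC18A3, the vesicular acetylcholine transporter, by 3.19 ± 0.25. Of the notochord list, 11 of 27 members were vegetal-higher, 7 were animal-higher and 9 did not pass (12 and 7 within the list), with adjusted p = 0.617. The remaining counts are given as vegetal-higher and animal-higher members of those measured, the same adjusted over the list alone, and adjusted p. They were oxidative phosphorylation (17 and 0 of 50, 11 and 0 alone, 0.466), with NDUFV2 higher by 1.78 ± 0.27, and germ line (6 and 1 of 17, 6 and 1 alone, 0.772), with Ddx4 higher by 2.86 ± 0.32. They were also the cell cycle (17 and 5 of 73, 15 and 5 alone, 0.812), with Plk1 higher by 2.60 ± 0.33, and heat shock (16 and 3 of 51, 14 and 3 alone, 0.812), with Hsp90b1 higher by 2.81 ± 0.26. For signalling they were Wnt (8 and 2 of 30, 8 and 2 alone, 0.812), with SFRP1 higher by 4.71 ± 0.42, and FGF (9 and 5 of 31, 9 and 5 alone, 0.918), with FGFR1 higher by 5.81 ± 0.29. Next were Notch and Hedgehog (13 and 7 of 38, 13 and 7 alone, 0.988) and TGF-beta (10 and 9 of 41, 10 and 9 alone, 0.527), with TLL1 higher by 5.61 ± 0.34. The last were the proteasome (9 and 2 of 40, 5 and 2 alone, 0.812), ribosomal proteins (2 and 1 of 78, 2 and 1 alone, 0.812), splicing (17 and 5 of 119, 11 and 5 alone, 0.812), meiosis (3 and 0 of 7, 4 and 0 alone, 0.527) and histones (0 and 0 of 9, 0 and 0 alone, 0.449). Of these, PSMD10 differed by -2.11 ± 0.53 (adjusted p = 0.0512 with the compared libraries alone) and Hnrnpdl by -3.37 ± 0.64.

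**Figure D2:**
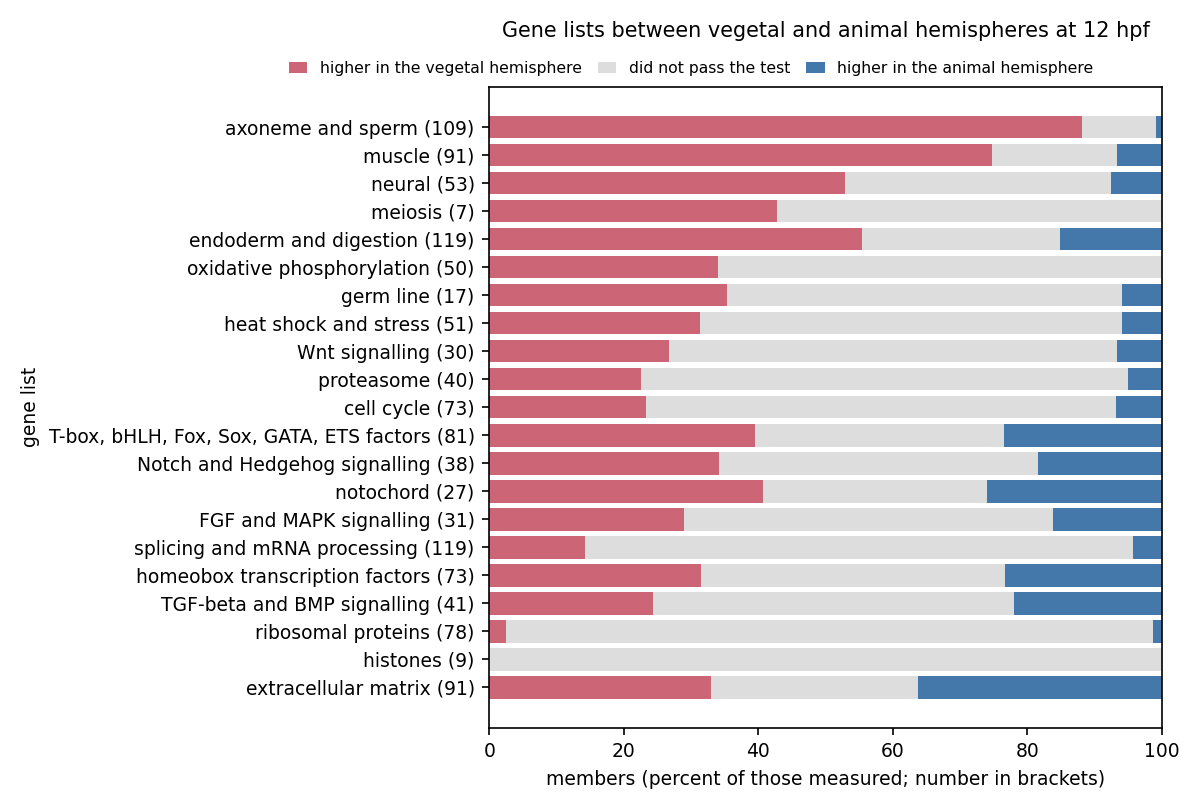
Percent of the measured members of each gene list that were vegetal-higher, animal-higher or not passed at 12 hpf (limma, adjusted over all unigenes, 4 libraries per hemisphere), with the number measured in brackets. The axoneme and sperm list has 96 vegetal-higher members of 109.

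The difference between hemispheres changed with time for 5589 unigenes (interaction in limma), 3869 with a difference shifted to the vegetal side by 12 hpf and 1720 to the animal side. The examples that follow were named for the size of their difference at one of the times, so an interaction was to be expected in them. ZIC4 went from 5.10 at the 8-cell stage to 0.27 at 12 hpf (interaction -4.83 ± 0.83, adjusted p = 5.46e-05) and a Wnt11 unigene from 3.51 to -0.01 (-3.51 ± 0.34, adjusted p = 1.29e-08). BOLL went from -0.12 to 8.25 (8.37 ± 0.60). Quantile normalization gave 2613 and 2691 unigenes in the same directions, with the median moved from 0.248 to -0.2. With the replicate number as a block within each time, 61 unigenes differed between hemispheres at the 8-cell stage, 8845 at 12 hpf and 6863 in the interaction. Without the 2 libraries that stand apart the interaction count was 6386 and the 8-cell count 61.

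In whole embryos, 12418 of 15697 unigenes differed between the 8-cell stage and 12 hpf, 8831 higher and 3587 lower at 12 hpf (n = 4 libraries each). Among genes chosen after their values were seen, the muscle genes Myl6 and Tnnt2 rose by 8.63 ± 0.33 and 7.53 ± 0.30. Psma1, a proteasome subunit, changed by -4.35 ± 0.19 from 555 ± 69.3 to 26.4 ± 4.15 RPKM. Under quantile normalization 4138 were higher and 5564 lower, and the median moved from 1.17 to -0.18.

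Hemispheres were also set against whole embryos, as the mean of the log2 values of both hemispheres minus the whole embryo. At the 8-cell stage no unigene passed in limma (97 with an unadjusted p under 0.05, fewer than chance gives) and 12 did without whole-embryo library 4. The list tests shifted nonetheless, relative to the other unigenes. The Wnt list shifted below the whole embryo (adjusted p = 4.36e-06, and 0.0416 with estimated correlation). So did those of ribosomal proteins (6.83e-05 and 0.659), extracellular matrix (6.83e-05 and 0.269) and endoderm (0.00066 and 0.48). The FGF (adjusted p = 0.0059, and 0.269 with estimated correlation) and axoneme lists (0.00731 and 0.659) shifted down too. The T-box to ETS (adjusted p = 0.0309, and 0.495 with estimated correlation) and notochord lists (0.0323 and 0.355) shifted down as well. The splicing list shifted above the whole embryo (adjusted p = 0.000268, and 0.495 with estimated correlation). The heat shock (0.0129 and 0.449) and cell cycle lists (0.0309 and 0.495) did so too. All of these but Wnt lost their call under quantile normalization, and those of Wnt (adjusted p = 0.0574), ribosomal proteins (0.0846), T-box to ETS factors (0.21) and notochord (0.0846) with hemispheres averaged as RPKM. The notochord call was lost with the block within each time as well (0.0567). Without the 2 libraries that stand apart, 9 of these 11 lists lost their call, the exceptions being Wnt and ribosomal proteins. At 12 hpf 3764 unigenes differed, 201 higher and 3563 lower in the hemispheres, and 863 with the hemispheres of a number averaged as RPKM, an alternative chosen after seeing the data. A mean of logs lies below the log of a mean for genes that differ between hemispheres. Quantile normalization gave 2015 higher and 2018 lower, with the median moved from -0.259 to 0.19.

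Muscle genes were lower in the hemispheres at 12 hpf than in whole embryos: 3 of 91 members were higher, 71 were lower and 17 did not pass (3 and 72 within the list). The muscle list had adjusted p = 1.75e-27, and 0.0783 with estimated correlation, and 42 were lower and 0 higher with hemispheres averaged as RPKM (adjusted p = 1.91e-17). As an example chosen after its values were seen, Tnnt2 stood at 0.0666 RPKM in animal, 9.05 ± 4.27 in vegetal and 207.5 ± 66.5 in whole samples (-6.00 ± 0.26). Homeobox factors (adjusted p = 0.00874, and 0.601 with estimated correlation), T-box to ETS factors (adjusted p = 0.00874, and 0.601 with estimated correlation) and axoneme genes (adjusted p = 0.0131, and 0.687 with estimated correlation) also lay below the whole embryo. Members lower numbered 32 of 73 for homeobox, 36 of 81 for T-box to ETS and 37 of 109 for axoneme, with 0 higher in each. Over the list alone these were 34, 41 and 39, with 2, 0 and 1 higher. Under quantile normalization the homeobox (adjusted p = 0.06) and axoneme (0.52) calls were lost, and with hemispheres averaged as RPKM the T-box call was lost (0.129) and the axoneme list lay above the whole embryo (2.63e-07). The splicing list, not called in the main fit (adjusted p = 0.0884), was called with the block within each time (0.0201).

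The staged series followed RNA from egg to juvenile in 12 steps, each stage set against the one before (n = 3 libraries each). Few unigenes passed at any single step of the first cleavages: 7 on fertilization, 0 at the 2-cell stage (limma, 213 at an unadjusted p under 0.05), 1 at the 4-cell and 4 at the 8-cell stage. Set against the egg instead, 535 were higher and 1166 lower at the 4-cell stage (102 and 625 by 4-fold or more), and 452 and 1407 at the 8-cell stage. At the 16-cell stage 77 rose and 28 fell, and at the 32-cell stage 24 rose and 306 fell. Between the 32-cell stage and 1.5 hpf 2156 rose and 563 fell, 999 and 171 of them by 4-fold or more. The tadpole step at 2.5 hpf had 364 rises and 229 falls, hatching at 3 hpf 4323 and 838, early organogenesis at 5 hpf 5380 and 1304, late organogenesis at 8 hpf 3549 and 2013, and the juvenile at 10 hpf 403 and 399. A first 4-fold rise over the egg came at 5 hpf for 2915 unigenes, at 3 hpf for 2056, at 8 hpf for 1999 and at 1.5 hpf for 706, of 8616 in all. Any difference among the 13 stages was found for 17380 of 18704 unigenes.

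The counts of several steps rested on single libraries. At the 16-cell step 105 became 64, 54 or 193 without 16-cell library 17, 18 or 46 and 66 without 8-cell library 30. At the 32-cell step 330 became 119 or 90 without 16-cell library 17 or 18 and 110 or 33 without 32-cell library 1 or 48. The tadpole step went from 593 to 377 or 291 without 1.5 hpf library 19 or 2 and to 338, 200 or 1098 without tadpole library 3, 32 or 4. Hatching went from 5161 to 3208 without tadpole library 4, to 2628 without hatched library 34 and to 7869 without hatched library 5, and the juvenile step from 802 to 528 without juvenile library 23 and to 2303 without 8 hpf library 21. The fertilization step went from 7 to 139 without fertilized library 10, to 89 without egg library 9 and to 0 without fertilized library 11 or 42 or egg library 29 or 41. With lane as a covariate the tadpole step gave 4380, the 32-cell step 501 and fertilization 0. At the tadpole step flow cell and stage cannot be told apart. With the spread taken from the compared libraries alone, hatching gave 17 (0 higher and 17 lower), 5 hpf 1048, 8 hpf 1606, the 16-cell step 23, the 32-cell step 1 and the step to 1.5 hpf 5643. That setting gave 0 for fertilization, the tadpole and the juvenile step and 1 for the 8-cell step. Quantile normalization evened out directions, to 1859 higher and 1885 lower at hatching and 2820 and 2981 at 5 hpf. It gave 2687 and 2869 at 8 hpf, 1237 and 1210 at 1.5 hpf and 36 and 23 at the 32-cell step.

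**Figure D3:**
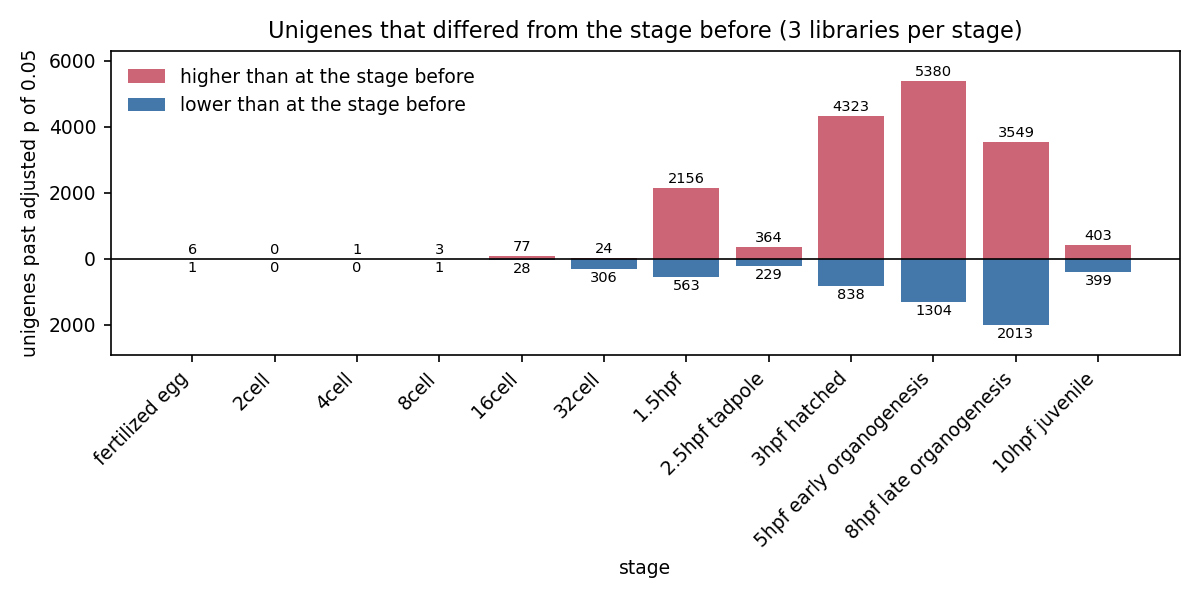
Number of unigenes that rose or fell at each step of the staged series (limma, adjusted p under 0.05; 3 libraries per stage), stages in order from the fertilized egg to the juvenile. The steps up to the 8-cell stage have 7 changes or fewer, and the step to 5 hpf has 6684. The order of the steps is that of the main fit: with the compared libraries alone the step to 1.5 hpf has the most.

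Between the unfertilized egg and the 2.5 hpf tadpole, the largest rises among unigenes with a symbol included CA4, Proz and the muscle genes Myl2 and Tpm1, and the largest falls Cs, Ckmt2 and Gata3 (n = 3 libraries each). CA4, a carbonic anhydrase, went from 0.207 ± 0.266 to 1073 ± 205 RPKM, a log2 change of 9.80 ± 0.58. Proz, a protein Z homologue, was listed at 0 in the egg and stood at 430.0 ± 78 RPKM in the tadpole. The myosin light chain Myl2 rose by 8.73 ± 0.53 and tropomyosin Tpm1 by 8.10 ± 0.49. Sspo, which in vertebrates forms a fibre in the neural canal, rose by 8.46 ± 0.50 and Hmcn1 by 8.45 ± 0.48. Rhag, an ammonium transporter, rose by 8.33 ± 0.48, ZFP36L1, which promotes mRNA decay, by 8.03 ± 0.31, the calcium sensor Ncs1 by 8.00 ± 0.56 and Tagln3 by 7.85 ± 0.43. The largest adjusted p of these rises was 6.39e-14. Cs, citrate synthase, went from 4185 ± 369.9 to 29.9 ± 11 RPKM (-7.14 ± 0.48), and Gapdh of glycolysis from 2006 ± 316 to 32.4 ± 12.7 (-5.98 ± 0.53). Transcription factors of the egg, Gata3 and NKX2-6, fell with changes of -6.62 ± 0.29 and -6.45 ± 0.33, and CDC34, a ubiquitin-conjugating enzyme, with -5.99 ± 0.44. Mitochondrial creatine kinase Ckmt2 (-7.02 ± 0.63), Calml3 (-6.29 ± 0.85), TMEM38B (-6.16 ± 0.47), Nme2 (-6.09 ± 0.59) and Prcp (-5.99 ± 0.53) fell as well, with the largest adjusted p at 2.56e-07. In all 4567 of 18704 unigenes differed, 2541 higher and 2026 lower in the tadpole, and 2279 by 4-fold or more (1170 and 1109). The libraries of 4227 of these did not overlap, nor, called or not, did those of 35.8% of all tested, against 10% by chance. Flow cell and stage cannot be told apart here, and with lane as a covariate estimated from the other stages 8779 differed, 2157 higher and 6622 lower. Under quantile normalization 2191 were higher and 2424 lower, with the median moved from 0.064 to -0.067.

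By list test, homeobox and T-box to ETS factors were called higher and oxidative phosphorylation and the proteasome lower in the tadpole. With an estimated correlation only the proteasome and histones kept a call. Of homeobox factors 48 of 79 members rose, 3 fell and 28 did not pass (49 and 3 within the list). The homeobox list had adjusted p = 1.09e-20, and 0.131 with estimated correlation. VAX1 rose by 6.09 ± 0.30, and SIX6 and Otx2 stood at 54.3 ± 10.7 and 82.2 ± 17.9 RPKM and were listed at 0 in the egg. Of T-box to ETS factors 44 of 87 members rose, 4 fell and 39 did not pass (49 and 9 within the list). The T-box to ETS list had adjusted p = 1.24e-10, and 0.379 with estimated correlation, with Tbx5 at 26.3 ± 10.4 RPKM in the tadpole. Of the muscle list 39 of 113 members rose, 2 fell and 72 did not pass (42 and 2 within the list). The muscle list had adjusted p = 7.98e-09, and 0.379 with estimated correlation, with Tnni3 at 219 ± 155 RPKM and listed at 0 in the egg. Of oxidative phosphorylation 1 of 51 members rose, 34 fell and 16 did not pass (1 and 35 within the list). The oxidative phosphorylation list had adjusted p = 3.36e-16, and 0.131 with estimated correlation, with Cox4i1 changed by -4.14 ± 0.31, ATP5H by -5.38 ± 0.50 and Sdhc by -5.55 ± 0.44. Of the proteasome 2 of 40 members rose, 27 fell and 11 did not pass (2 and 28 within the list). The proteasome list had adjusted p = 2e-15, and 0.00475 with estimated correlation, with Psma5 changed by -5.09 ± 0.37 and PSMB3 by -3.43 ± 0.23. Of histones 8 of 9 members rose, 0 fell and 1 did not pass (8 and 0 within the list). The histone list had adjusted p = 2.68e-07, and 0.0294 with estimated correlation, with H1F0 at 95.3 ± 25.5 RPKM from 1.63 ± 0.245. Of ribosomal proteins 34 of 80 members rose, 0 fell and 46 did not pass (56 and 0 within the list). The ribosomal list had adjusted p = 7.72e-08, and 0.821 with estimated correlation, and 10 rose under quantile normalization. Of FGF signalling 11 of 32 members rose, 2 fell and 19 did not pass (11 and 2 within the list). The FGF list had adjusted p = 0.00527, and 0.801 with estimated correlation. Of Wnt signalling 10 of 30 members rose, 2 fell and 18 did not pass (10 and 3 within the list). The Wnt list had adjusted p = 0.00679, and 0.801 with estimated correlation, with FZD6 up by 4.26 ± 0.25. Of the neural list 14 of 53 members rose, 2 fell and 37 did not pass (15 and 2 within the list). The neural list had adjusted p = 0.00679, and 0.825 with estimated correlation. Of the notochord list 8 of 29 members rose, 1 fell and 20 did not pass (10 and 1 within the list). The notochord list had adjusted p = 0.0449, and 0.825 with estimated correlation, with T up by 4.45 ± 0.34 and Foxa2 by 5.81 ± 0.35. Of the axoneme list 24 of 150 members rose, 4 fell and 122 did not pass (22 and 4 within the list). The axoneme list had adjusted p = 0.0449, and 0.825 with estimated correlation. The cell cycle list shifted down: 7 of 75 members rose, 11 fell and 57 did not pass (7 and 11 within the list). The cell cycle list had adjusted p = 0.0449, and 0.825 with estimated correlation, with CDC25C changed by -4.66 ± 0.33 and Cdc25a by 3.57 ± 0.34. With lane as a covariate the neural (adjusted p = 0.489), cell cycle (0.132), axoneme (0.887) and notochord (0.365) calls were lost, and quantile normalization ended those of cell cycle (0.951) and axoneme (0.389). The cell cycle call was lost too without members matched by spelling alone (0.0516) and with the symbols of the second sheet added (0.127). The lane covariate added calls of splicing (0.00134, 44 members up and 32 down) and endoderm (0.048, 21 up and 33 down), higher relative to the other unigenes, and of the germ line (0.048, 1 up and 12 down), lower. Lists without a call are given as members that rose and fell of those measured, the same alone, and adjusted p. They were endoderm (21 and 6 of 154, 18 and 4 alone, 0.0544), heat shock (4 and 8 of 52, 4 and 8 alone, 0.108) and germ line (1 and 2 of 17, 1 and 2 alone, 0.202). Extracellular matrix (15 and 3 of 154, 14 and 3 alone, 0.286), meiosis (2 and 0 of 8, 2 and 0 alone, 0.402) and Notch and Hedgehog genes (4 and 2 of 47, 4 and 2 alone, 0.628) were not called either. Neither were splicing (12 and 6 of 124, 10 and 6 alone, 0.628, and 0.000726 under quantile normalization), TGF-beta (5 and 6 of 51, 5 and 6 alone, 0.698) and mitochondrial genome (0 and 0 of 8, 0 and 0 alone, 0.881).

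From the 3 hpf hatched larva to the 10 hpf juvenile, the period of organogenesis, the largest rises among unigenes with a symbol included DNER, LYG2 and the digestive protease CTRB2, and the largest falls Sspo, CA4 and Hmcn1 (n = 3 libraries each). DNER, a Notch ligand of the nervous system in mammals, went from 0.62 ± 0.24 to 9799 ± 3029 RPKM (12.53 ± 0.38). The chymotrypsin CTRB2 rose by 10.72 ± 0.63, CTRL by 9.88 ± 0.83, the trypsin-like PRSS3P2 by 9.63 ± 0.71 and the lysosomal protease Ctsl by 10.11 ± 0.65. LYG2, a lysozyme, rose by 11.02 ± 0.71, ITIH1 by 10.59 ± 0.33, Tecta by 10.18 ± 0.37, the prostaglandin synthase Hpgds by 9.61 ± 0.46 and the adhesion receptor ADGRL1 by 9.56 ± 0.50. The largest adjusted p of the rises was 1.77e-12. Sspo went from 2342 ± 366 to 0.55 ± 0.0599 RPKM (-10.55 ± 0.50), CA4 changed by -10.40 ± 0.58, Hmcn1 by -10.27 ± 0.48 and Rhag by -7.43 ± 0.48, all of them genes named above for their rise to the tadpole. Gap junction proteins Gja10 and Gja4 fell (-8.04 ± 0.40 and -7.09 ± 0.36), and so did the ferritin Fth1 (-7.92 ± 0.56), the myosin heavy chains MYH6 (-7.53 ± 0.52) and Myh8 (-6.96 ± 0.59) and the endocytic receptor CUBN (-7.50 ± 0.43), with the largest adjusted p at 1.79e-12. In all 10839 of 18704 unigenes differed, 6524 higher and 4315 lower in the juvenile, and 5136 by 4-fold or more (3491 and 1645). The libraries of 8778 of these did not overlap, nor, called or not, did those of 51.1% of all tested, against 10% by chance. Under quantile normalization 4628 were higher and 5991 lower, with the median moved from 0.1 to -0.164. Here too flow cell and stage cannot be told apart, and with lane as a covariate 7837 were higher and 1767 lower.

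Among the lists called for the juvenile, endoderm, matrix and oxidative phosphorylation were higher, and cell cycle, splicing and homeobox factors were lower. With an estimated correlation none of the calls was kept. Of endoderm and digestion 111 of 154 members rose, 17 fell and 26 did not pass (111 and 17 within the list). The endoderm list had adjusted p = 1.91e-10, and 0.32 with estimated correlation, with CHIT1, a chitinase, up by 6.02 ± 0.21 and Prss44 by 7.48 ± 0.28. Of the extracellular matrix 91 of 154 members rose, 28 fell and 35 did not pass (92 and 29 within the list). The matrix list had adjusted p = 0.00156, and 0.703 with estimated correlation, with the fibrillin Fbn2 up by 7.59 ± 0.31 and the collagen Col27a1 by 6.42 ± 0.29. Of oxidative phosphorylation 37 of 51 members rose, 4 fell and 10 did not pass (37 and 4 within the list). The oxidative phosphorylation list had adjusted p = 0.00974, and 0.703 with estimated correlation, with Cox4i1 up by 2.50 ± 0.31. Of the cell cycle 2 of 75 members rose, 59 fell and 14 did not pass (2 and 63 within the list). The cell cycle list had adjusted p = 9.04e-15, and 0.32 with estimated correlation, with KIF23 changed by -4.58 ± 0.32, CDC25A by -5.79 ± 0.41 and cyclin CCNB3 by -6.00 ± 0.52. Of splicing 3 of 124 members rose, 84 fell and 37 did not pass (4 and 86 within the list). The splicing list had adjusted p = 5.73e-12, and 0.32 with estimated correlation, with SF3B3 changed by -2.16 ± 0.25. Of the proteasome 1 of 40 members rose, 21 fell and 18 did not pass (1 and 21 within the list). The proteasome list had adjusted p = 2.22e-06, and 0.303 with estimated correlation, with Psmc1 changed by -3.37 ± 0.25. Of Wnt signalling 2 of 30 members rose, 17 fell and 11 did not pass (2 and 17 within the list). The Wnt list had adjusted p = 7.95e-05, and 0.396 with estimated correlation, with the receptor FZD6 changed by -4.22 ± 0.25. Of the notochord list 1 of 29 members rose, 18 fell and 10 did not pass (1 and 19 within the list). The notochord list had adjusted p = 7.95e-05, and 0.485 with estimated correlation, with T changed by -2.44 ± 0.34. Of homeobox factors 11 of 79 members rose, 33 fell and 35 did not pass (11 and 33 within the list). The homeobox list had adjusted p = 0.00171, and 0.703 with estimated correlation, with Otx2 changed by -4.70 ± 0.37. Of the T-box to ETS factors 17 of 87 members rose, 34 fell and 36 did not pass (17 and 34 within the list). The T-box to ETS list had adjusted p = 0.013, and 0.703 with estimated correlation. Of histones 0 of 9 members rose, 5 fell and 4 did not pass (0 and 5 within the list). The histone list had adjusted p = 0.00974, and 0.386 with estimated correlation, with H1F0 changed by -3.06 ± 0.37. Of the germ line 1 of 17 members rose, 10 fell and 6 did not pass (1 and 10 within the list). The germ line list had adjusted p = 0.0137, and 0.703 with estimated correlation, with Piwil1 changed by -2.97 ± 0.63 (adjusted p = 0.225 with lane as a covariate). Of the mitochondrial genome 0 of 8 members rose, 8 fell and 0 did not pass (0 and 8 within the list). The mitochondrial genome list had adjusted p = 0.0241, and 0.703 with estimated correlation, and MT-ND4, MT-CO3, MT-CYB and MT-ND5 lost their calls without hatched library 34 (adjusted p = 0.647, 0.856, 0.783 and 0.865), with lane as a covariate (0.112, 0.152, 0.124 and 0.101) and with the compared libraries alone (0.25, 0.285, 0.27 and 0.286). Quantile normalization ended those of MT-ND4 (0.0606), MT-CYB (0.0646) and MT-ND5 (0.0755). With lane as a covariate the calls of oxidative phosphorylation (adjusted p = 0.726) and germ line (0.0651) were lost, and quantile normalization ended those of T-box to ETS factors (0.0658) and the mitochondrial genome (0.207). Lists without a call, given as before, were axoneme (69 and 18 of 150, 70 and 18 alone, 0.0519, and 0.0125 under quantile normalization), meiosis (0 and 3 of 8, 0 and 3 alone, 0.0652) and heat shock (13 and 19 of 52, 13 and 19 alone, 0.0652). The Notch and Hedgehog list was not called (17 and 10 of 47, 17 and 10 alone, 0.327), although Dll1 rose by 8.52 ± 0.31. Muscle genes were not called (48 and 31 of 113, 48 and 31 alone, 0.56), although TNNT3 rose by 7.66 ± 0.31. TGF-beta genes were not called (21 and 12 of 51, 21 and 12 alone, 0.597), and BMP1 rose by 6.48 ± 0.45. Neural genes were not called (20 and 9 of 53, 20 and 9 alone, 0.599), and the synapsin SYN2 rose by 7.80 ± 0.42. Ribosomal proteins (2 and 2 of 80, 1 and 0 alone, 0.599) and FGF (11 and 8 of 32, 11 and 8 alone, 0.627) were not called. With lane as a covariate the ribosomal (adjusted p = 2.44e-09) and heat shock lists (0.0235) were called downward, with 0 and 8 members higher and 2 and 6 lower, and the axoneme list upward (0.00527).

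Adult females and males (n = 2 libraries each, all on the same lane) differed most, among unigenes with a symbol, in genes such as CKB and NASP on the female and SLC25A5 and Ckmt2 on the male side. CKB, a creatine kinase, stood at 16070.0 ± 10992 RPKM in females and 2.45 ± 1 in males (12.03 ± 1.12), and NASP, a histone chaperone, differed by 10.98 ± 1.30. The cyclin Ccnb1 was female-higher by 9.51 ± 0.81, the tubulin Tuba1b by 9.72 ± 0.98, Calml3 by 9.84 ± 1.04, the tight junction protein Cldn19 by 9.41 ± 0.42, Trim2 by 9.19 ± 0.51 and TNXB by 9.14 ± 0.77. In males the ADP/ATP carrier SLC25A5 stood at 33183 ± 4691 RPKM against 3.54 ± 2.98 in females (-13.00 ± 1.57), and Ckmt2 and CKM, creatine kinases, differed by -12.97 ± 1.56 and -12.78 ± 1.48. Odf3, of sperm tail outer dense fibres, stood at 8190.2 ± 997 RPKM in males and 0.78 ± 0.586 in females (-12.20 ± 1.30), Cfap20 differed by -11.56 ± 1.01 and Tssk6, a kinase of the testis, by -10.37 ± 0.84. CNFN (3744 ± 947 RPKM in males), Glud1 (-11.03 ± 0.99), Plscr1 (-10.69 ± 0.84) and another Tuba3a unigene (-10.57 ± 0.99) were male-higher too. The largest adjusted p was 9.46e-09 among the female-higher and 1.34e-08 among the male-higher genes. In all 8753 of 18704 unigenes differed, 7516 female-higher and 1237 male-higher, and 6544 by 4-fold or more (5646 and 898). The libraries of 8575 of these did not overlap, nor, called or not, did those of 69.9% of all tested, against 33.3% by chance. The 10 most abundant unigenes held 50.9% of the RPKM of male library 26 and 27.4% of male library 25. Under quantile normalization 3947 were female-higher and 3552 male-higher, with the median moved from 0.73 to -0.036.

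By list test the axoneme and sperm list was called male-higher, and splicing, cell cycle and germ line female-higher. With an estimated correlation all 4 calls were lost. Of the axoneme and sperm list 36 of 150 members were female-higher, 80 were male-higher and 34 did not pass (41 and 80 within the list). The axoneme list had adjusted p = 1.52e-26, and 0.282 with estimated correlation, and quantile normalization gave 10 female-higher and 96 male-higher. SPEF2 differed by -4.39 ± 0.17, Rsph1 by -8.20 ± 0.36 and MNS1 by -6.95 ± 0.32. Of splicing 116 of 124 members were female-higher, 1 was male-higher and 7 did not pass (116 and 1 within the list). The splicing list had adjusted p = 1.85e-16, and 0.282 with estimated correlation, with SF3B3 at 36.9 ± 3.49 RPKM in females and 0.322 ± 0.148 in males. Of the cell cycle 61 of 75 members were female-higher, 3 were male-higher and 11 did not pass (63 and 3 within the list). The cell cycle list had adjusted p = 2.21e-06, and 0.965 with estimated correlation, with CDK1 female-higher by 7.56 ± 0.52 and CDC25C by 5.76 ± 0.40. Of the germ line 13 of 17 members were female-higher, 0 were male-higher and 4 did not pass (15 and 0 within the list). The germ line list had adjusted p = 0.013, and 0.965 with estimated correlation, with Ddx4 female-higher by 5.15 ± 0.53 and Pum2 by 4.83 ± 0.62. Of oxidative phosphorylation 7 of 51 members were female-higher, 8 were male-higher and 36 did not pass (7 and 6 within the list), and the list test was shifted to males (adjusted p = 5.21e-05, and 0.965 with estimated correlation), with Cycs, cytochrome c, at -9.07 ± 0.62 and Ndufs1 at 7.13 ± 0.69. Of the proteasome 1 of 40 members was female-higher, 3 were male-higher and 36 did not pass (1 and 2 within the list). Its median was 0.00 and its mean 0.13, while its test shifted to males relative to other unigenes (adjusted p = 0.013, and 0.965 with estimated correlation). Quantile normalization ended the calls of oxidative phosphorylation (adjusted p = 0.263) and the proteasome (0.848). Lists without a call, as female-higher and male-higher members of those measured, the same alone, and adjusted p, were homeobox (6 and 1 of 79, 5 and 1 alone, 0.0741), T-box to ETS factors (25 and 2 of 87, 23 and 2 alone, 0.721) and heat shock (30 and 2 of 52, 31 and 2 alone, 0.088). Meiosis (2 and 2 of 8, 2 and 2 alone, 0.0894), TGF-beta (23 and 2 of 51, 23 and 2 alone, 0.315) and neural genes (9 and 0 of 53, 9 and 0 alone, 0.33) were not called. Endoderm (44 and 7 of 154, 41 and 6 alone, 0.468), Wnt (10 and 0 of 30, 10 and 0 alone, 0.553) and notochord genes (12 and 1 of 29, 12 and 1 alone, 0.556) were not called. Extracellular matrix (57 and 3 of 154, 54 and 3 alone, 0.896), histones (2 and 0 of 9, 2 and 0 alone, 0.896) and muscle genes (39 and 1 of 113, 36 and 1 alone, 0.896) were not called. Notch and Hedgehog (13 and 1 of 47, 13 and 0 alone, 0.896) and FGF genes (11 and 1 of 32, 11 and 1 alone, 0.899) were not called. Neither were ribosomal proteins (39 and 0 of 80, 41 and 0 alone, 0.472) and the mitochondrial genome (0 and 0 of 8, 0 and 0 alone, 0.0529). Gata3 stood at 150.2 ± 7.7 RPKM in females and was listed at 0 in males, NKX2-6 was female-higher by 6.62 ± 0.41, and of the meiosis genes Hormad1 differed by -4.83 ± 0.31 and SPO11 by -2.86 ± 0.42. Under quantile normalization 14 endoderm members were female-higher and 53 male-higher (adjusted p = 0.00726), 58 ribosomal members female-higher and 1 male-higher (3.52e-11), and 0 meiosis members female-higher and 4 male-higher (0.042). With lane as a covariate the mitochondrial genome (adjusted p = 0.0465) and homeobox lists (0.0473, 7 members female-higher and 1 male-higher) were called toward males relative to other unigenes. Without members matched by spelling alone both were called (0.0463 and 0.0431).

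Adults, as the mean of both sexes, differed from the 10 hpf juvenile in 11199 of 18704 unigenes, 1958 higher and 9241 lower in adults. Chosen after its values were seen, Hpgds stood at 1958 ± 105.5 RPKM in juveniles, 0.938 in females and 3.07 in males (-9.49 ± 0.43, adjusted p = 4.97e-19). Under quantile normalization 5069 were higher and 4602 lower in adults, with the median moved from -0.824 to 0.056.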

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

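The tests of the 3 patterns weighed in this part were all chosen after the results were seen, whereas the counts over other splits of the samples were planned, except those within numbers. In groups of 4 libraries, a library was singled out where its gap to the nearest other was too large a share of the range by Dixon's test, which chance gives in about 1 in 20 groups, and 7 of 88 groups tested had one. These concerned the number of unigenes at 1 RPKM or more in whole-embryo 8-cell library 6 (9493), the relative depth of whole-embryo 12 hpf library 4 (0.807), the mean correlation with its group of vegetal 12 hpf library 3 (0.872) and of whole-embryo 12 hpf library 6 (0.92). The others were PIM1 in animal 8-cell library 5 (0.848 RPKM), Otx2 in animal 8-cell library 4 (0.133 RPKM) and Ust in vegetal 12 hpf library 3 (41.2 RPKM). The hemisphere difference changed with time for 5589 unigenes, by the interaction term. In data outside the comparisons, 11 columns of a second staged sheet differ from the first.

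Vegetal 12 hpf library 3 held unigenes of the animal side. Over the unigenes called animal-higher without it, its median level was 43.8% of the animal mean, against 2.42% to 10.1% in the other vegetal libraries, which is consistent with animal RNA mixed into it. A swap with the whole-embryo library of the same number is argued against by that library's own level of 53%, beside 45.6% to 52.4% in the other whole-embryo libraries. A whole-embryo library labelled vegetal is argued against as well, since unigenes higher in whole embryos than in hemispheres stood at 13.7% of the whole-embryo mean in it, against 82.7% to 115% in the whole-embryo libraries. The design gives no group for a biological explanation, and none was tested.

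Whole-embryo 8-cell library 6 held unigenes of 12 hpf embryos. Of 943 with 100 RPKM or more in a 12 hpf library and under 1 RPKM in every other 8-cell library, 77.5% were at 1 RPKM or more in it. Mixing with RNA or reads of a 12 hpf library may account for it, and the highest rank correlation was 0.734, with animal 12 hpf library 6, but the levels relative to that library varied too widely to decide. Embryos further on in development are argued against by the hemispheres of the same number, where at most 3.73% of 991 reached 1 RPKM, a set limited by the 8-cell libraries of numbers 3, 4 and 5 only. Greater depth is argued against by the deepest other 8-cell library, where 0.422% of 947 did, a set limited by the remaining ones. No biological explanation was tested beyond stage.

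Whole-embryo 8-cell libraries 3, 5 and 6 held less of the 62 vegetal-higher unigenes than the hemispheres of the same number, by medians of 1.67, 1.64 and 2.32 on the log2 scale, whereas whole-embryo library 4 held more. Collection of the hemispheres, and of whole embryos 4, at a later division could account for this: other unigenes that rose at the 16-cell stage of the staged set were higher in the hemispheres too, by a median of 1.21 or more in each of the 3. Whether separation raised these RNAs stays open: in number 4 the intact embryos lay above their own hemispheres by 1.12, but that is a single library and the one offered above as collected later. Lower depth of the whole-embryo libraries is argued against by relative depths of 0.973, 1.06 and 1.32 in numbers 3, 5 and 6, beside 0.865 to 1.42 in the hemispheres of these numbers. A difference in stage between samples of the same label is a hypothesis here, found and tested on the same data.

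Other splits of the same libraries were counted for each comparison of at least 3 libraries per group. Since numbers pair the hemisphere libraries within each time, splits that exchange labels only within a number were counted too. For the 8-cell hemispheres 1 of 35 splits, the real one, gave 63 unigenes and the highest other gave 42, and for 12 hpf 1 of 35 gave 7566 and the highest other 5293. The splits that part all 4 pairs are 8, too few for a share under 0.05, with a highest other of 0 at 8 cells and 3754 at 12 hpf. For the interaction 2 of 100 splits gave 5589 or more, the highest other 6138, a split that moves 4 of the 8-cell libraries. Within numbers 5 of 100 did so, up to 5767, but the 4 others keep or exchange all 12 hpf hemispheres and so hold their real difference. Without such splits 1 of 90 did. For hemispheres against whole embryos at 12 hpf 4 of 100 splits gave 3764 or more (highest other 5497). Within numbers 10 of 81 did (highest other 7429), 8 of the 9 others calling 3 or 4 libraries of a hemisphere whole, which holds the hemisphere difference too, and without such splits 2 of 63 did. Within numbers neither share was under 0.05 before such splits were left out, by a rule set after the results were seen. Chance is thus not excluded for the interaction or for hemispheres against whole embryos at 12 hpf. It can be excluded for whole embryos over time (1 of 35, 12418 against 4423) and for any stage difference (1 of 100, 17380 against 5143). The same holds for adjacent stages (1 of 100, 21968 against 14004). For hemispheres against whole embryos at 8 cells the real count of 0 is reached by all 100 splits by necessity, so the count decides nothing, and the highest other, 871, points to a structure of the samples. For tadpole against egg (4567, highest other 9) and juvenile against hatched larva (10839, highest other 3206) the 10 splits are too few for a share under 0.05.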

How the results depend on the processing

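Tests with the lane covariate, the second staged sheet, blocks within each time, changed lists, 2 libraries left out, hemispheres averaged as RPKM or unigenes measured at both times were chosen after the results were seen, and the others were planned. Of 418 named genes with a call, 398 kept it with each library left out in turn, 396 under quantile normalization, 409 with a pseudocount of 0.1, 383 with the compared libraries alone and 287 of those in the staged set with the lane covariate, where 3 changed sign: Psmc3ip (0.13) and RPS21 (-0.2) for the juvenile and Psmc3ip (-0.31) for the tadpole. Of 55 called lists, 4 kept their call with an estimated correlation, which are Wnt at 8 cells in both hemisphere comparisons and the proteasome and histones in the tadpole, and 34 under quantile normalization. The axoneme list in hemispheres against whole embryos at 12 hpf changed direction with hemispheres averaged as RPKM (2.63e-07), which removes the lowering that a mean of logs gives to genes unequal between hemispheres. Between 8-cell hemispheres the matrix list was called without the 2 libraries that stand apart (0.0353), the matrix (0.0325) and oxidative phosphorylation lists (0.0189) without members matched by spelling alone and the endoderm list with the symbols of the second sheet (0.0265). Without the 2 libraries the calls added were, for hemispheres against whole embryos at 12 hpf, Wnt (0.0483), matrix (0.028), proteasome (0.0317) and ribosomal proteins (0.028). In that comparison oxidative phosphorylation and splicing were called under quantile normalization (0.0311 and 0.000161) and with hemispheres averaged as RPKM (0.00192 and 5.11e-06). Quantile normalization, which evens out directions, gave 51 vegetal-higher and 4 animal-higher unigenes at 8 cells. Over adjacent stages it gave 9733 higher and 9760 lower against 16286 and 5682. For the other comparisons the values stand in the report.

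Counts moved by over 1.5 times as follows. The compared libraries alone leave fewer residual degrees of freedom and change the spread. They gave 34 unigenes at 8 cells, 2466 between hemispheres and whole embryos at 12 hpf and 8340 over adjacent stages (steps in the report). Hemispheres averaged as RPKM gave 863 at 12 hpf. For hemispheres against whole embryos at 8 cells a pseudocount of 0.1 gave 1 and no minimum gave 1, and leaving out a library gave 0 to 12. The lane covariate gave 8779 for the tadpole, and the cause was not tested. The second staged sheet gave 1172 for the tadpole, 4436 for the juvenile, 4444 for the sexes, 6578 for adults and 5238 over adjacent stages, and since 11 of its columns hold another library's values times a constant, these are no limit of the results. The odds ratio of sharing between 8 cells and 12 hpf was 0.367 among 4-fold differences (p = 0.05 by Fisher's exact test), where fewer unigenes are compared, and 2.38 among unigenes measured at both times (exact p = 0.0797, or 0.398 for the animal side), so a share below chance is not shown. With the replicate number as a block the counts were 63 at 8 cells, 8208 at 12 hpf, 6185 for the interaction, 12856 for whole embryos over time, and 0 and 4325 for hemispheres against whole embryos, and with blocks within each time 61, 8845, 6863, 11630, 0 and 4988. Blocks within each time added calls of H1F0 (0.00268) and H1f0 (0.0283) at 12 hpf and Anln (0.0371) at 8 cells, and apart from these and those in the report they changed no call of a named gene or list. Leaving out each library in turn gave 45 to 66 at 8 cells, 6728 to 7969 at 12 hpf, 4837 to 6319 for the interaction, 11845 to 12262 for whole embryos over time, 3029 to 4562 for hemispheres against whole embryos at 12 hpf, 3556 to 4903 for the tadpole, 9070 to 11695 for the juvenile, 6961 to 8697 for the sexes, where the lone library of a sex is assumed to vary like the other groups, 10060 to 11335 for adults, 17091 to 17743 for any stage and 19894 to 25817 over adjacent stages. In simulated data changes of 1 on the log2 scale were recovered in 25.4% or fewer, so small changes may have been missed.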

Other observations

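The tests and examples in this part were all chosen after the results were seen. Unigenes that share a symbol peaked at different times in the staged set (mean RPKM of 3 libraries, or 2 for adults). A CA4 unigene was at 1657 RPKM in the unfertilized egg, 27.4 at the 8-cell stage and 1907 in adult females, another CA4 unigene was at 774 at 1.5 hpf, 2234 in the hatched larva and 6.92 at 5 hpf, and another CA4 unigene was at 205.7 in the hatched larva and 1616 at 5 hpf. Otx2 showed the same kind of difference: the Otx2 unigene that was vegetal-higher at 8 cells was at 78.6 RPKM at 1.5 hpf and 1.15 at 5 hpf, while others named Otx2 were at 0.71 and 0.358 at 1.5 hpf and 150.6 and 78.7 at 5 hpf.

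The authors' deposited table of transcription factors covers 420 of the unigenes tested in the hemisphere set. At the 8-cell stage 2 of the 62 vegetal-higher unigenes were on it, Foxa2 and SNAI2, against 1.66 by chance (odds ratio 1.21, Fisher's exact p = 0.683, two-sided). At 12 hpf 110 factors were vegetal-higher against 138 by chance (odds ratio 0.719, exact p = 0.00315) and 70 were animal-higher against 64.5 (odds ratio 1.11, exact p = 0.45). ZIC4, PAX3, SALL1 and Otx2, named for 8 cells, are not among the members counted there.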
